A study of Mus musculus with 3 samples.

How the data were processed

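Total RNA of 2 EpiSC lines (E3 and T9) and 1 ESC line (OG2) was extracted on columns with DNA digestion, amplified from 400 ng with 12 h of in vitro transcription and hybridised to 1 Illumina mouse bead array per line, per the labels' protocols. Groups were taken from the titles of the samples. E3 was EpiSC replicate 1, T9 EpiSC replicate 2 and OG2 the only ESC sample, the replicate numbers being names only.

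The deposited scanner tables give, per the file headers, a signal intensity for each probe, the standard error of that intensity over the probe's beads, and a detection p-value. The signal intensity values deposited by the authors are linear, were not background-subtracted (lowest values 70.5, 66.7 and 69.3 in E3, T9 and OG2) and were not normalized between arrays. The detection p-value the authors deposited moves in steps of 1 in 798. Per the submitters' processing notes BeadStudio was used; its version and a genome build are not given in the sources used here, and no coordinates are printed. A further table of the authors' processed intensity values for the same arrays, with medians of 81.0, 80.8 and 80.8, ranked the probes of each array exactly as the scanner signals did (Spearman's rho of 1). Its scale was linear, its lowest listed values were close to 7.00, lower ones were left blank, and its normalization method is not given in the sources used here. It was used as an alternative only, with blank values set to the lowest listed value before taking log2.

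Gene names came from the probe table of the platform. Of the 25697 probes, 23978 had 1 gene symbol, 0 had several and 1719 had none and stayed unnamed. Symbols were looked up through the gene identifier in a RefSeq gene table, which held 23962 of them and changed 0.

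From the scanner signals, background was corrected with limma's nec function (normal-exponential convolution with the background inferred from the detection p-values) with an offset of 16, values were taken to log2 and quantile normalized between arrays. The offset pulls differences of dim probes towards 0, so folds of dim genes are understated. Probes with a detection p under 0.01 on at least 1 array were tested, 12603 in all, of which 9347 were detected on all 3 arrays, 820 in both EpiSC lines only, 808 in ESC only and 717 had no gene name. lmFit and eBayes of limma compared the 2 EpiSC arrays with the ESC array (two-sided, Benjamini-Hochberg adjusted over all tested probes, threshold 0.05). A gene was represented by its probe with the highest mean level, which gave 8688 genes. Where no probe of a gene was detected on a side, the fold is given as "at least", with the dim side set to the lowest normalized level among detected probes of that array or the gene's own level, whichever was higher. The p-values measure the spread between 2 lines of different background and cover no repeat culture of any line.

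E3 against T9, and each EpiSC line against OG2, have 1 array on each side and no test. They were described with a size rule of 2-fold, and bead standard errors give the error within an array only. For genes 2-fold apart in both EpiSC lines, 100 simulations with no change, drawn from the E3 and T9 differences, showed what the shared ESC array gives by itself.

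In all, 23 gene lists were fixed before the data were examined: naive pluripotency, core pluripotency, post-implantation epiblast, primitive streak and mesendoderm, neural, Activin/Nodal, FGF/ERK, LIF/STAT3, Wnt targets, germline, DNA methylation, fibroblast, trophoblast, extraembryonic endoderm, epithelial, mesenchymal, glycolysis, MHC class I, imprinted, Xist and Y-linked, cell cycle, stress and housekeeping. Of their 292 entries, 260 had a probe and 202 were measured. Each list is given by its counts past the limma threshold, its counts adjusted over the list alone, and its median log2 difference. The median was set against 10000 random lists of the same size, matched on mean level in 20 bins, as a description of these arrays and not as a test. Medians at the bounds were set against random lists with the same bounds applied. Tbx3, Rhox6 and other members are also expressed outside the cell type their list is named for.

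The genes named were also fixed by rule beforehand. For EpiSC against ESC these were genes past the threshold with the same direction in both lines, the 8 highest and 8 lowest detected on all 3 arrays by the smaller of the line differences, and the 6 brightest detected on only 1 side. Between the EpiSC lines they were the 6 largest differences each way among genes detected on both arrays, and the 4 brightest detected in only 1 line. Members of the fixed lists could be named with their values.

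The test was checked on simulated arrays of 12603 probes for the EpiSC against ESC comparison, 200 of them changed. A change of 4 on the log2 scale was recovered for 90.5% with 10 false calls, and changes of 0.5, 1 and 2 for 0. In 20 simulated lists of 12 genes, the median percentile was 36.0 with no shift and 99.2 with a shift of 0.5.

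Alternatives were no background correction, an offset of 50, median scaling, cyclic loess, detection on all 3 arrays, no detection filter, the authors' processed values, an intensity trend in the prior variance, 1 probe per gene, the mean of a gene's probes, leaving out either EpiSC line, and a bead error criterion. The analysis used R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.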

Results

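Gene expression was measured on Illumina bead arrays in 3 mouse pluripotent cell lines, with 1 array per line. E3 and T9 are epiblast stem cell (EpiSC) lines, a cell type that resembles the epiblast of the implanted embryo. OG2 is an embryonic stem cell (ESC) line, a cell type that resembles the preimplantation epiblast. E3 and OG2 have a hybrid genetic background and T9 a 129 background. The EpiSC lines were kept on inactivated fibroblast feeders with FGF2 at 5 ng/ml. OG2 was kept without feeders on gelatin with the MEK inhibitor PD0325901 (1 uM), the GSK3 inhibitor CHIR99021 (3 uM) and LIF (1000 U). Per the labels, the EpiSC were collected with collagenase IV and little feeder material, and OG2 directly on its dish, so cell type, medium, feeders and harvest changed together. Each array held 25697 probes, of which 10791 were detected in E3, 11171 in T9 and 10768 in OG2. The median bead standard error of a detected probe was 4.18% of its signal in E3, 4.17% in T9 and 4.36% in OG2. The number of arrays limits the precision of all comparisons.

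The first comparison set the 2 EpiSC lines against the ESC line and asked how their expression profiles differ when each cell type is kept in its own standard medium. The transcription factors of naive pluripotency Esrrb, Zfp42, Klf4 and Tbx3 fell in EpiSC, Esrrb by 6.58 ± 0.50 on the log2 scale (limma SE, 2 EpiSC arrays against 1 ESC array), a 95.8-fold difference. The epiblast growth factor Fgf5, the epiblast POU factor Pou3f1 and the Nodal target and antagonist Lefty1 rose, Pou3f1 by 3.90 ± 0.26 (14.9-fold). Of 15 measured glycolysis genes 4 rose, among them the enzyme genes Ldha (7.46-fold) and Tpi1 (8.98-fold), and the germline gene Dazl fell below background in both EpiSC lines. Pou5f1, the POU factor shared by both pluripotent states, lay at 12.65 in E3, 12.41 in T9 and 12.53 in OG2 (normalized log2 intensity).

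Of 12603 tested probes, 145 passed a Benjamini-Hochberg adjusted p of 0.05 with limma, 36 of them higher and 109 lower in EpiSC. They stood for 28 and 85 named genes, and 11 of the probes had no gene name here. The share that was higher was 24.8%, against 36.5% (138 higher, 240 lower) with median scaling and 35.5% (122 and 222) with cyclic loess in place of quantile normalization. The smallest adjusted p was 0.0317 and the smallest fold among these probes 6.003. An unadjusted p under 0.05 was found for 2928 probes, where 630 would be expected by chance.

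Among genes past the threshold and detected on all 3 arrays, ranked by the smaller line difference, the early growth response factor Egr1 stood first and rose by 7.03 ± 0.26 on the log2 scale (130-fold, limma adjusted p = 0.0317). Its level was 12.02 in E3 and 12.14 in T9 against 5.06 in OG2. The thyrotropin-releasing hormone gene Trh followed with 5.71 ± 0.27 (52.2-fold). The aldolase gene Aldoc (20.4-fold), the RNA-binding protein gene Rbmx (19.3-fold), the pregnancy-specific glycoprotein gene Psg23 (19.3-fold), Pou3f1, Lefty1 (14.5-fold) and the carbonic anhydrase gene Car4 (9.46-fold) completed the first 8 of this ranking, with adjusted p between 0.0317 and 0.0344. Of genes past the threshold that were detected in both EpiSC lines and not in ESC, the 6 brightest were the sulfotransferase gene Chst1, the carbonic anhydrase gene Car14, the prolyl hydroxylase gene Egln3, the kinase gene Pim2, Fgf5 and Cmtm8. They were at least 31.4-fold, 26.1-fold, 20.03-fold, 17.9-fold, 12.3-fold and 12.2-fold higher, in that order, with adjusted p from 0.0317 to 0.0444.

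In the same ranking of lower genes the X-linked homeobox gene Rhox5 stood first and fell by 6.95 ± 0.55 on the log2 scale (124-fold, limma adjusted p = 0.0357). Its level was 5.01 in E3 and 6.13 in T9 against 12.52 in OG2. Esrrb, the oocyte protein gene Ooep (56.5-fold), Zfp42 (61.7-fold), Dppa4 (48.4-fold), the myosin light chain gene Mylpf (38.7-fold), the beta-mannosidase gene Manba (29.0-fold) and Mreg (23.7-fold) followed, with adjusted p between 0.0317 and 0.0342. The 6 brightest genes past the threshold that were detected in ESC and in neither EpiSC line were Rbmxl2, 2210409E12Rik, Fam25c, the germ cell RNA-binding protein gene Dazl, Tbx3 and Fmr1nb. They were at least 60.9-fold, 36.0-fold, 35.8-fold, 31.6-fold, 26.3-fold and 24.8-fold lower, each with an adjusted p of 0.0317. Rbmx and Rbmxl2 are related genes, and binding of either transcript to the probe of the other was not tested.

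**Figure D1:**
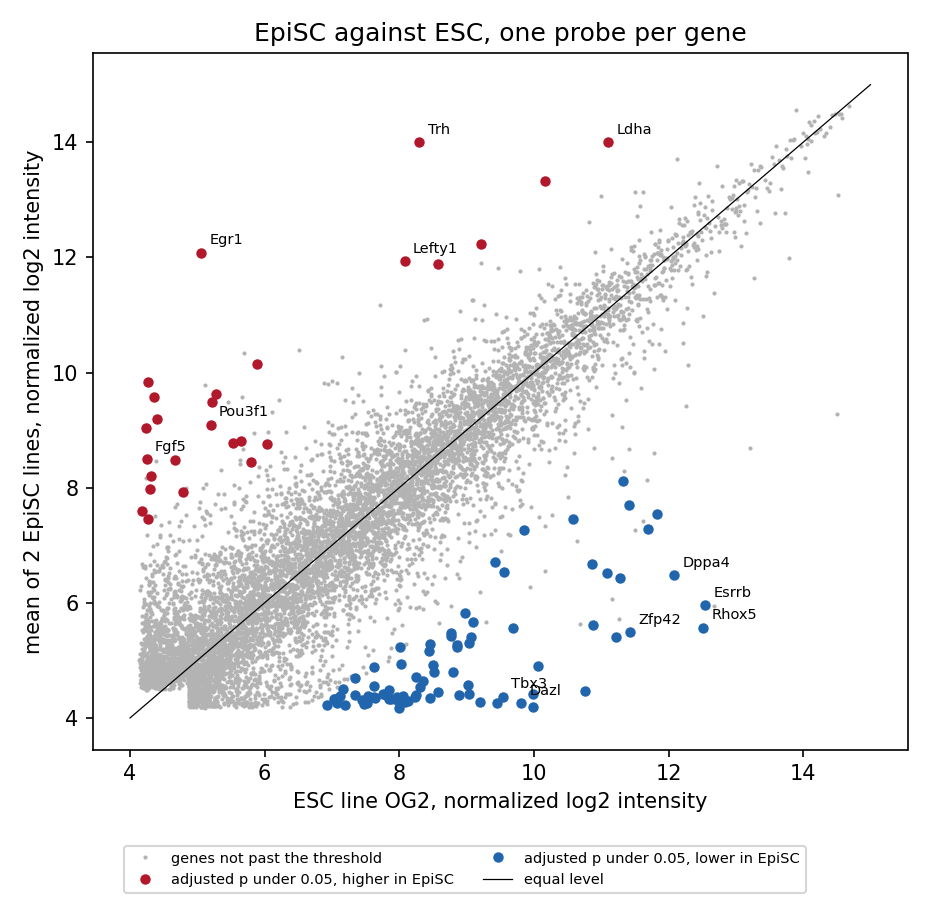
Normalized log2 intensity of 8688 genes in the ESC line OG2 (horizontal axis) and as the mean of the EpiSC lines E3 and T9 (vertical axis), 1 probe per gene, with the line of equal levels. Coloured points are genes past the limma threshold, 26 higher (red) and 80 lower (blue) in EpiSC, and Egr1 stands furthest above the line at 5.06 in OG2.

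Of 15 measured genes of the naive pluripotency list, 6 fell and 9 did not pass the test. The 6 were Esrrb, Zfp42, Tbx3, Klf4 (13.3-fold), the AKT cofactor gene Tcl1 (at least 16.7-fold) and the adhesion molecule gene Pecam1 (8.42-fold). Adjusted over the list alone, 13 members passed, all lower. The list median was -3.56 on the log2 scale (-4.19 in E3, -3.28 in T9), and 0 of 10000 random lists of matched brightness had a median as low. Dppa5a was 37.1-fold lower with an adjusted p of 0.0873, and its level was 8.32 in E3 and 10.25 in T9. Gbx2 and Nr5a2 lay near the ESC level in T9 (9.31 and 8.64 against 9.25 and 8.41), while in E3 Gbx2 lay at 5.05 and Nr5a2 was not above background.

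None of the 10 measured core pluripotency genes passed the test over all probes, and adjusted over the list alone 1 was higher and 1 lower. Those were the RNA-binding protein gene Lin28a, with a log2 difference of 1.59 ± 0.28, and Nanog, with -1.45 ± 0.26. Sox2 differed by -0.91 ± 0.27 and Sall4 by -0.19 ± 0.27. The list median was -0.10 (0.043 in E3, -0.13 in T9), and 2168 of 10000 random lists had a median as low. A second Pou5f1 probe gave levels of 12.45, 12.21 and 12.30 in E3, T9 and OG2.

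Of 10 measured post-implantation epiblast genes, 2 rose (Fgf5 and Pou3f1) and 8 did not pass the test. Adjusted over the list alone, 7 were higher. The homeobox gene Otx2 was 14.7-fold higher in the EpiSC mean (adjusted p = 0.0781) and Zic2 4.90-fold (adjusted p = 0.115). Grhl2 went the other way, with a log2 difference of -1.43 ± 0.83. The list median was 2.06, or 1.92 with genes not above background at their bound, and 0 of 10000 random lists had a median as high.

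**Figure D2:**
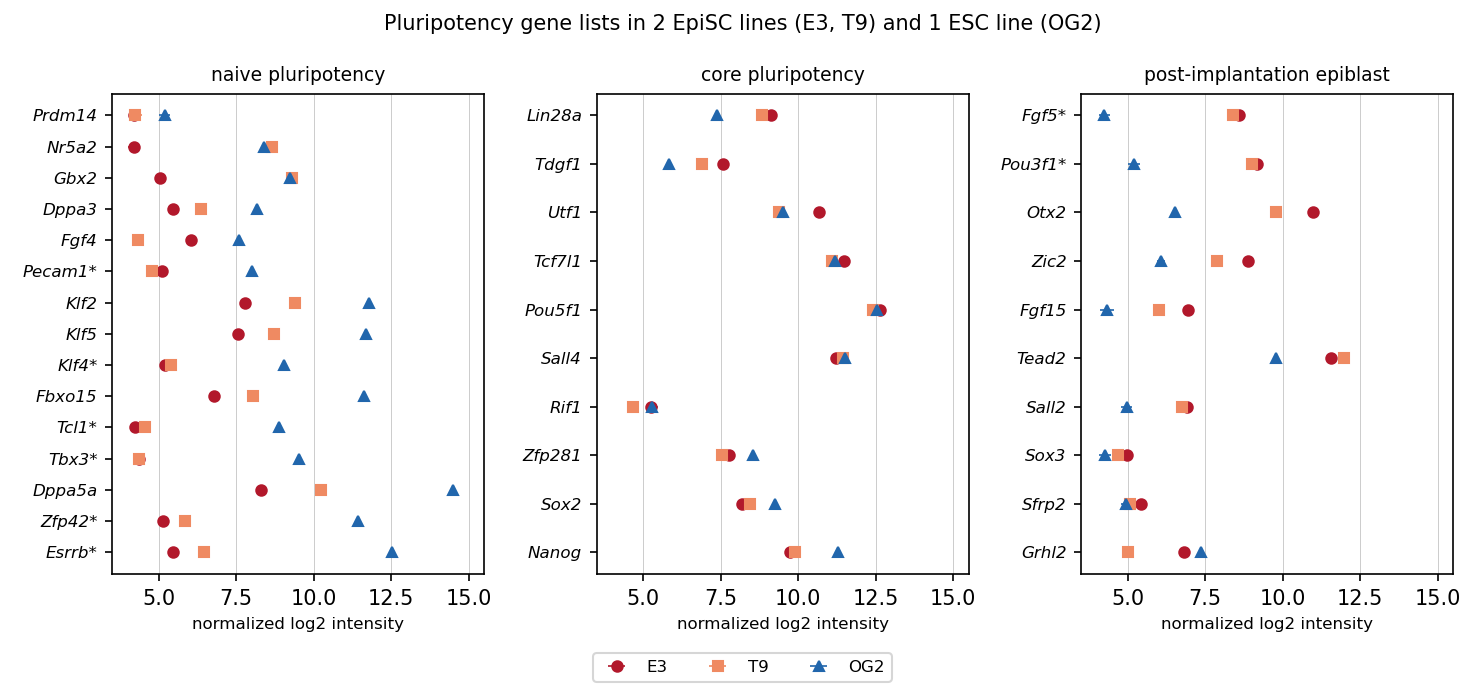
Normalized log2 intensity (horizontal axis) of each measured gene of the naive, core and post-implantation lists in E3, T9 and OG2, with bars for the bead standard error and an asterisk on genes past the limma threshold. Naive genes sit to the left in the EpiSC lines, apart from Gbx2 and Nr5a2 in T9, with a median difference of -3.56. Pou5f1 lies between 12.41 and 12.65 in all lines.

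Of 9 measured germline genes, 3 fell: Dazl, the transcription factor gene Taf7l (at least 9.05-fold) and the piRNA pathway gene Asz1 (at least 6.56-fold). Adjusted over the list alone, 6 were lower. The list median was -1.54 (-0.97 at the bounds). Of 4 measured trophoblast genes, the homeobox genes Rhox9 (at least 13.5-fold) and Rhox6 (at least 4.78-fold) fell, and 3 were lower adjusted over the list alone. That list had a median of -2.74 (-2.46 at the bounds). For both lists 0 of 10000 random lists had a median as low, and at the bounds 1 for germline and 0 for trophoblast genes. These counts carry little weight, since the random lists were not matched on detection. Dazl, Nanos3, Stk31, Stra8, Asz1, Piwil2 and Taf7l were detected in ESC only, as were Gata3, Rhox6 and Rhox9. The detection filter thus fixed their direction. Only Ifitm3 and Tfap2c were detected on all 3 arrays.

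The lists of early differentiation did not pass the test in any member. Primitive streak and mesendoderm genes had a median of 0.71 over 12 members, 0.23 in E3 and 1.12 in T9, and 28 random lists of 10000 were as high (1780 for E3 alone and 0 for T9 alone). At the bounds, set for the random lists too, the median was 0.39, 0.069 in E3 and 0.89 in T9, with 28, 3352 and 0 random lists as high. Eomes, Mixl1, Lhx1, Foxa2, Cer1, Mesp1, Wnt3, Fgf8 and Tbx6 were detected in T9 and not in OG2. The detection filter thus fixed their direction for T9, and the random lists were not matched on detection. Of the members detected on all 3 arrays, Gsc differed by 1.04, Snai1 by 0.43 and Hhex by -0.94 in the EpiSC mean. Adjusted over the list alone, 0 members passed. Fgf8 was at least 18.5-fold higher in the EpiSC mean, with an adjusted p of 0.0988. Only 3 neural genes were measured, with a median of 0.95 (0.50 in E3, 1.41 in T9), and adjusted over the list alone the filament gene Nes was higher and Tubb3 lower. The 7 measured genes of extraembryonic endoderm had a median of -0.12 (0.13 in E3, -0.054 in T9), and the laminin gene Lama1 alone was lower adjusted over the list alone, at -2.44 ± 0.31.

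Among signalling lists, 1 member each of Activin/Nodal and FGF/ERK rose and none fell. In the Activin/Nodal list that was Lefty1, and adjusted over the list alone 4 of 8 members were higher and 1, Inhba, lower. The receptor gene Acvr2b differed by 1.24 ± 0.25 and Nodal by -0.02 ± 0.26, and the list median was 1.15 (2 of 10000 random lists as high). In the FGF/ERK list Egr1 rose, and 5 of 11 members were higher adjusted over the list alone. Fos was 25.6-fold higher in the EpiSC mean (limma adjusted p = 0.0604), while the ERK feedback genes lay on both sides, from Dusp4 at 1.61 ± 0.40 to Phlda1 at -1.37 ± 0.62. That list had a median of 0.76, and 48 random lists were as high. The median was 0.26 in E3 alone, with 2183 random lists as high, and 1.12 in T9 alone, with 3.

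No member of the LIF/STAT3 or Wnt lists passed the test over all probes. The 9 measured LIF/STAT3 genes had a median of -0.67, with 86 of 10000 random lists as low, and adjusted over the list alone Bcl3 was lower at -1.80 ± 0.30. The feedback inhibitor gene Socs3 differed by -1.33 ± 0.41. The 9 measured Wnt targets had a median of 0.28, but -0.48 in E3 and 0.79 in T9, and adjusted over the list alone Notum was at least 2.31-fold lower.

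Of 15 measured glycolysis genes, 4 rose, 0 fell and 11 did not pass the test. The 4 were the phosphofructokinase gene Pfkl (9.94-fold), Tpi1, Ldha and the lactate exporter gene Slc16a3. The Slc16a3 probe used lay at 7.63 in E3, 7.27 in T9 and not above background in OG2, and a second Slc16a3 probe went the other way, at 5.04 in OG2 and not above background in EpiSC. Adjusted over the list alone, 9 were higher and 2 lower, the latter Hk1 (-1.39 ± 0.25) and Pfkp (-1.17 ± 0.27). The glucose transporter gene Slc2a1 was 4.20-fold higher in the mean with an adjusted p of 0.0641. The list median was 1.32, 1.30 in E3 and 1.34 in T9, and 0 of 10000 random lists of matched brightness were as high.

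**Figure D3:**
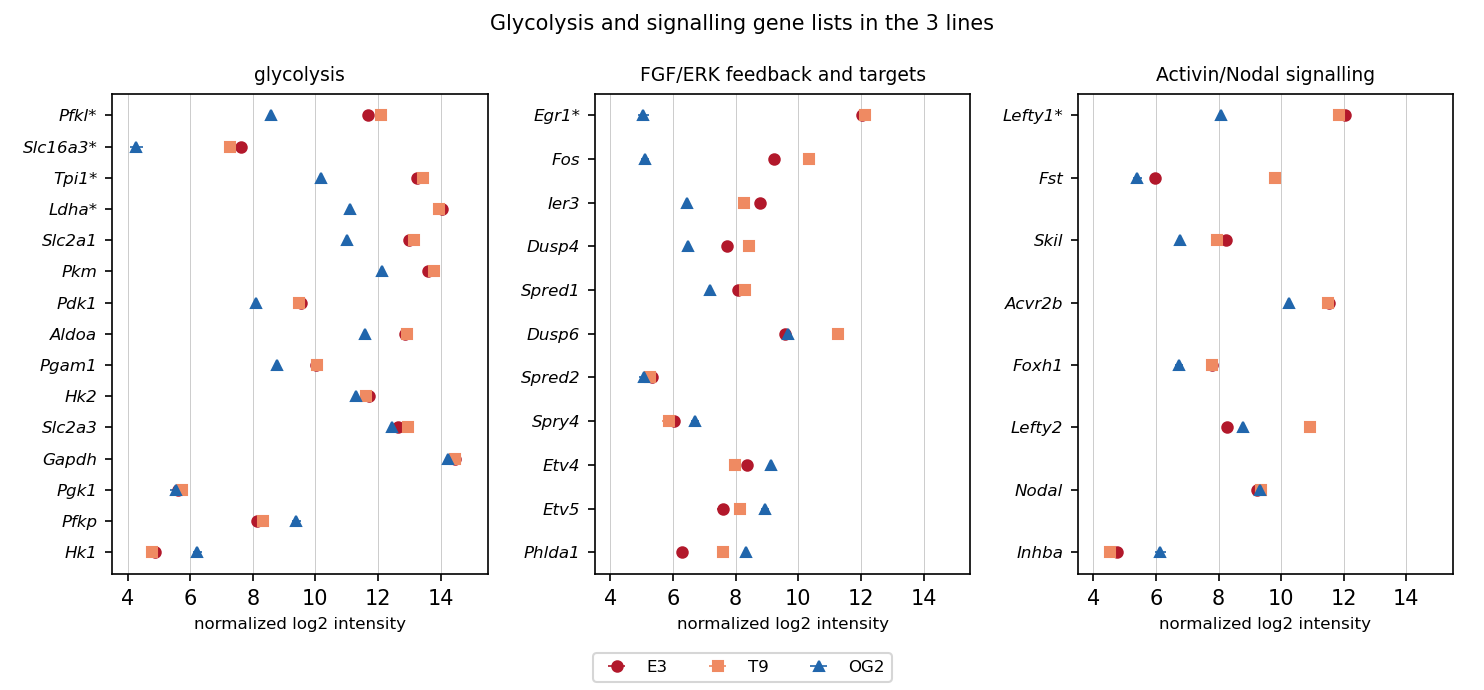
Normalized log2 intensity (horizontal axis) of each measured gene of the glycolysis, FGF/ERK and Activin/Nodal lists in E3, T9 and OG2, with bars for the bead standard error and an asterisk on genes past the limma threshold. Egr1 sits at 12.02 and 12.14 in the EpiSC lines against 5.06 in OG2, and Pfkl, Tpi1, Ldha and Slc16a3 are the starred glycolysis genes.

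Fibroblast genes, which would mark feeder cells, gave 1 gene past the threshold, and it was lower in EpiSC. That was the collagen crosslinking enzyme gene Lox (at least 11.5-fold lower), the only one of 15 measured members to pass, also adjusted over the list alone. The collagen gene Col1a1 lay at 6.39 in OG2, 5.16 in T9 and below background in E3. The list median was -0.25, -0.57 in E3 and 0.10 in T9.

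In the other lists no member passed the test over all probes. The 10 epithelial genes had a median of 0.58 (0.41 at the bounds), 0.92 in E3 and 0.25 in T9, and the keratin gene Krt19 was higher adjusted over the list alone. The 4 mesenchymal genes had a median of -0.67, but -1.54 in E3 and 0.51 in T9, and none passed over all probes or adjusted over the list alone. MHC class I genes had a median of 1.24 over 8 members (0.88 at the bounds), with 4 higher adjusted over the list alone, among them H2-T23 at 1.57 ± 0.26. The 12 imprinted genes had a median of 0.78 (0.73 at the bounds, and 0.051 among members detected on all 3 arrays), 0.41 in E3 and 0.97 in T9, with 4 higher and 1 lower adjusted over the list alone. Grb10 was 6.51-fold higher in the mean with an adjusted p of 0.0525.

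The 5 measured genes of DNA methylation had a median of -0.39, and adjusted over the list alone Tdg was higher and the cofactor gene Dnmt3l lower, at -4.25 ± 0.93. The methyltransferase gene Dnmt3b differed by 1.64 ± 0.63. The 9 cell cycle genes had a median of 0.18, but 0.49 in E3 and -0.27 in T9, with 2 higher and 2 lower adjusted over the list alone, the higher ones Ccnd1 and Mycl. The 8 stress genes had a median of -0.42, with 2 higher and 1 lower adjusted over the list alone. Chac1 differed by 2.17 ± 0.27 and Ddit3 by -1.35 ± 0.25. The 5 housekeeping genes had a median of 0.36, and none passed over all probes or adjusted over the list alone.

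By size alone, 588 genes were at least 2-fold higher and 614 at least 2-fold lower in both EpiSC lines than in ESC, and 9 genes lay 2-fold or more on opposite sides. With genes not above background at their bound, 505 were higher and 543 lower. With no change simulated, the shared ESC array gave a mean of 93.0 genes higher in both and 93.4 lower. Independent lists of the same lengths would share 102 and 82.8. Part of the excess over these can come from the ESC array that both differences share, and with 1 such array it could not be split.

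The second comparison set the 2 EpiSC lines against each other, with 1 array each and therefore no test. T9 had higher levels than E3 of primitive streak genes, several Wnt targets and mesenchymal genes, and E3 had higher levels of most epithelial genes. Fgf8, a growth factor of the primitive streak, was 4.25-fold higher in T9, and the Wnt target Sp5 23.6-fold. The epithelial cadherin gene Cdh1 was 2.94-fold higher in E3 and the claudin gene Cldn6 4.51-fold. At least 2-fold differences were found for 209 genes higher in E3 and 294 higher in T9 (192 and 244 at the bounds). The SD of log2 differences over all tested probes was 0.532 between E3 and T9, against 0.949 between E3 and OG2 and 0.951 between T9 and OG2. Pearson's r across these probes, which are not independent replicates, was 0.967, 0.894 and 0.893.

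The genes furthest above T9 in E3 were Cops8 (14.7-fold), Espn (13.2-fold), Tomm22 (13.1-fold), Pclaf (9.64-fold), Atf4 (8.44-fold) and Map7d3 (6.21-fold). Apart from Espn each rests on 1 tested probe, and probe sequences were not checked for variants between the genetic backgrounds. Tomm22 lay at 9.04 in OG2 and 5.35 in T9, and Atf4 at 9.76 and 6.80. The brightest detected in E3 and not in T9 were the Y-linked Eif2s3y (at least 12.7-fold), Rab25 (at least 9.64-fold), Ap1m2 (at least 9.57-fold) and Twistnb (at least 6.38-fold). The genes furthest above E3 in T9 were Sp5, the homeobox gene Gbx2 (19.1-fold), the Activin antagonist gene Fst (14.4-fold), Erdr1 (13.6-fold), the imprinted growth factor gene Igf2 (8.46-fold) and Meis2 (7.92-fold). Each of these also rests on 1 tested probe with an unchecked sequence. The brightest detected in T9 and not in E3 were Nckap1l (at least 16.7-fold), the nuclear receptor gene Nr5a2 (at least 13.7-fold), Actc1 (at least 7.19-fold) and Xist (at least 6.91-fold). Eif2s3y lay at 8.45 in E3, 8.22 in OG2 and below background in T9, and Xist at 7.65 in T9 and below background in the other lines. The list of Xist and 3 Y-linked genes had a median of -0.72 between EpiSC and ESC (-0.29 for E3, -0.94 for T9), and 0 of its members passed the test. Between E3 and T9 its median was 0.43 (0.13 at the bounds), with Xist on the T9 side and Eif2s3y on the E3 side. Kdm5d was detected in E3 (4.89) and not in T9, and Uty was not above background in either EpiSC line. Members of this list went opposite ways, so its median describes no shared shift.

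All 12 measured primitive streak genes were higher in T9, 5 of them at least 2-fold with genes not above background at their bound and 10 by more than 3 bead standard errors, which cover technical error within an array only. Eomes, Mixl1, Foxa2, Mesp1, Wnt3 and Tbx6 were detected in T9 only, so the detection filter fixed their direction. Gsc, Lhx1, Cer1, Fgf8, Snai1 and Hhex were detected in both lines. Their values of E3 minus T9 were -0.93, -0.87, -0.60, -2.09, -1.11 and -1.02, in that order. The median of E3 minus T9 over all 12 was -1.02 (-0.92 at the bounds), and 0 of 10000 random lists of matched brightness were as low. The random lists were not matched on detection, so this count includes the effect of the filter. The median was -1.03 (-0.74 at the bounds) for 9 Wnt targets, with Lef1 at -1.37, Axin2 at -1.03 and Nkd2 at 0.18 on the E3 side. Of these targets, Cdx1 and Notum were not above background in either EpiSC line, and Apcdd1 was not in E3. Cdx2 was detected in T9 only, so the filter fixed its direction. For 4 mesenchymal genes the median was -1.56 (-1.51 at the bounds), with Vim at -2.49 and Zeb1 at -2.22. For 10 epithelial genes it was 1.01 (0.97 at the bounds), with 6 higher in E3 by more than 3 bead standard errors, and Krt8 (-0.70) and Krt19 (-0.87) on the T9 side. Fibroblast genes were also higher in T9, with a median of -0.65 (-0.37 at the bounds), the actin gene Acta2 at -2.11 and the surface antigen gene Thy1 at 2.03 on the E3 side.

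The naive list had a median of -0.89 between E3 and T9, with 8 of 15 members higher in T9 and 1 higher in E3 by more than 3 bead standard errors, while the growth factor gene Fgf4 was at least 2.38-fold higher in E3. Imprinted genes had a median of -0.74 and MHC class I genes of -0.66. Post-implantation epiblast genes (0.33, or 0.28 at the bounds) and core pluripotency genes (0.27) were on the E3 side. The remaining medians were -0.48 for neural, 0.03 for Activin/Nodal, -0.23 for FGF/ERK, 0.01 for LIF/STAT3 and -0.05 for germline genes. They were 0.02 for DNA methylation, -0.24 for trophoblast, -0.22 for extraembryonic endoderm and -0.04 for glycolysis genes (0.082 with median scaling). Cell cycle genes had a median of -0.32, stress genes of 0.07 and housekeeping genes of -0.09. Most of the measured germline and trophoblast genes were not above background in either EpiSC line.

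**Figure D4:**
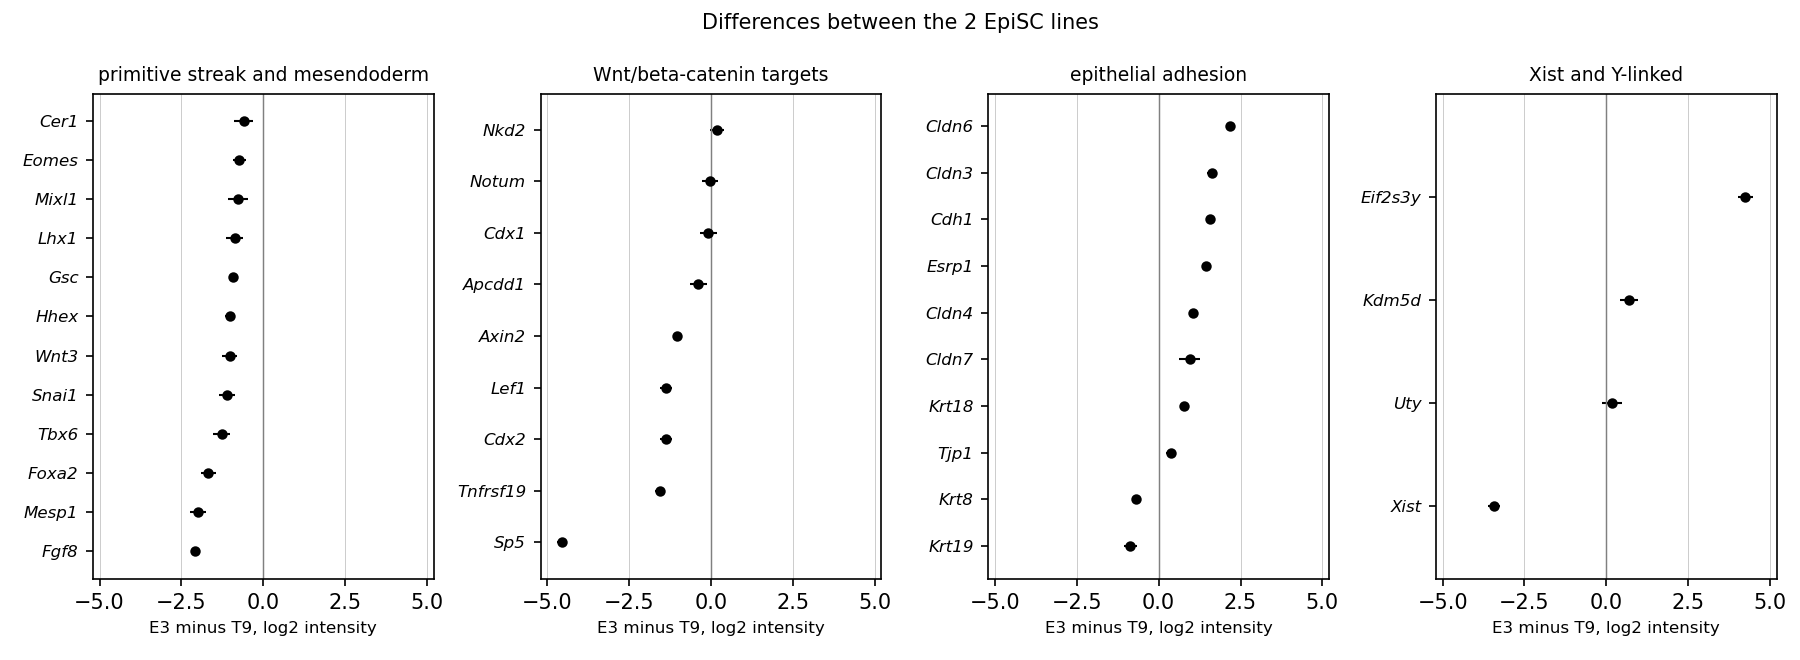
Log2 difference between E3 and T9 (horizontal axis, positive where E3 is higher) for each measured gene of the primitive streak, Wnt, epithelial and sex-linked lists, with bars for the combined bead standard error of both arrays. All 12 primitive streak genes lie below 0, with a median of -1.02, some of them measured only through detection in T9.

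The test for EpiSC against ESC had 1 residual degree of freedom per probe and 2.97 more from the prior, took its spread from 2 lines of different background, and assumed that the lone ESC array varies like them. The calls depended on the setting: 0 probes passed without the detection filter (4462 at an unadjusted p under 0.05) and 0 with the authors' processed values (2899), while an intensity trend in the prior gave 92 higher and 164 lower.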

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

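No tested result reversed under any alternative, and all 145 probes past the threshold kept their direction wherever they were tested. All settings used the same 3 arrays, and each of these probes differed at least 6.003-fold. Of the 145, 120 still passed without background correction, 97 with the offset of 50, and 0 without the detection filter or with the authors' values. All 145 passed with median scaling, cyclic loess and the intensity trend. The number of calls moved with the processing, and the cause was not tested. Probes higher and lower in EpiSC (36 and 109) numbered 138 and 240 with median scaling, 122 and 222 with cyclic loess, and 92 and 164 with an intensity trend in the prior variance. Without the detection filter and with the authors' processed values limma called 0 and 0 (4462 and 2899 probes at an unadjusted p under 0.05, smallest adjusted p 0.105 and 0.160). An offset of 50 gave 21 higher, and detection on all 3 arrays 58 lower, the latter with fewer probes tested (9347). For named genes 64 values between EpiSC and ESC stayed on their side without passing, 227 were unchanged in call and 5 moved; between E3 and T9, 86 were within the spread and 64 moved.

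Genes 2-fold higher and lower in both EpiSC lines (588 and 614) numbered 227 and 271 without background correction, 316 and 368 with the offset of 50, and 960 and 992 with the authors' values. Results with the authors' values depend in part on the floor set for blank probes. Detection on all 3 arrays gave 361 lower, and with only 1 EpiSC line 941 to 945 were higher. Genes 2-fold higher in E3 and in T9 (209 and 294) numbered 56 and 108 without background correction, 94 and 155 with the offset of 50, 133 and 153 with detection on all 3 arrays, and 593 and 685 with the authors' values. The SD of log2 differences (E3 against OG2, T9 against OG2, E3 against T9) was 0.617, 0.616 and 0.326 without background correction, 0.711, 0.710 and 0.382 with the offset of 50, and 0.947, 0.948 and 0.537 with median scaling. It was 0.943, 0.946 and 0.536 with loess, 0.854, 0.846 and 0.472 with detection on all 3 arrays, and 0.676, 0.676 and 0.389 without the filter. It was 1.28, 1.29 and 0.767 with the authors' values and 0.945, 0.946 and 0.525 with the mean of a gene's probes.

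List medians between EpiSC and ESC without background correction were naive -2.67, post-implantation 1.24, Activin/Nodal 0.86, LIF/STAT3 -0.30, germline -0.71, trophoblast -1.80, glycolysis 1.21, MHC 0.50, imprinted 0.32, Xist and Y-linked -0.25. The offset of 50 gave post-implantation 1.52, LIF/STAT3 -0.43, germline -0.75 and MHC 0.64. The authors' values gave post-implantation 2.57, primitive streak 1.40, LIF/STAT3 -1.11, germline -2.62, epithelial 1.17, glycolysis 1.39, MHC 1.81, and Xist and Y-linked -1.49. Detection on all 3 arrays gave LIF/STAT3 -0.86, germline -0.75 (Ifitm3 alone) and imprinted 0.051, and left the Xist and Y-linked list without a value. Glycolysis was 1.39 with median scaling, 1.27 with loess and 1.27 with the mean of probes, which put LIF/STAT3 at -0.49. With either EpiSC line left out, the median ranged from -0.13 to 0.043 for core, 0.82 to 1.21 for Activin/Nodal, -1.83 to -1.51 for germline, -0.054 to 0.13 for extraembryonic endoderm and 0.24 to 0.38 for housekeeping genes. It ranged from 0.23 to 1.12 for primitive streak, 0.50 to 1.41 for neural, 0.26 to 1.12 for FGF/ERK, 0.25 to 0.92 for epithelial, 0.41 to 0.97 for imprinted, and -0.94 to -0.29 for Xist and Y-linked genes. The sign also turned with the line for Wnt targets (-0.48 to 0.79), fibroblast (-0.57 to 0.098), mesenchymal (-1.54 to 0.51) and cell cycle genes (-0.27 to 0.49).

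Between E3 and T9, medians without background correction were naive -0.43, primitive streak -0.45, fibroblast -0.25, MHC -0.30 and imprinted -0.35. The offset of 50 gave primitive streak -0.64 and fibroblast -0.31, and the authors' values post-implantation 0.68, primitive streak -1.64 and fibroblast -1.12. Detection on all 3 arrays gave germline -2.17 and trophoblast -2.42, values of single genes (Ifitm3 and Tfap2c), and mesenchymal -2.22. The mean of probes gave LIF/STAT3 -0.36 and housekeeping 0.37, and median scaling glycolysis 0.082, all 3 on the other side of 0 from medians near 0.

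No paired analysis was possible because each line was cultured and measured once. Slide as a block was not run, since the sources used here give no slide, and leaving out an EpiSC line left no residual degrees of freedom, so those settings give values without a test. Signal over background limits dim genes: the median signal of a detected probe was 197, 191 and 192 in E3, T9 and OG2, over array medians of 89.2, 88.6 and 87.5.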

Other observations

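Several genes past the limma threshold belong to none of the fixed lists and are named here after their values were seen. In EpiSC the mTORC1 inhibitor gene Ddit4 rose by 3.02 ± 0.25 on the log2 scale, the secreted glycoprotein gene Stc2 by 2.64 and the immune checkpoint ligand gene Cd276 by 2.74, and the trunk development gene Vrtn was at least 6.60-fold higher. The water channel gene Aqp3 fell by 5.17 with E3 not above background, the small heat shock protein gene Hspb1 fell by 4.28, the apolipoprotein gene Apoe fell by 3.21 and the alkaline phosphatase gene Alpl fell by 2.59, and the peptidase gene Dpp4 was at least 20.8-fold lower. The largest limma adjusted p among these genes was 0.0471 (Alpl) and the smallest 0.0317 (Aqp3, Dpp4 and Hspb1).

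Between E3 and T9, some genes had 1 probe that departed from the other probes of the same gene by at least 2 on the log2 scale. Among 2021 probes of 894 genes this held for 6, of which 5 were lower in T9 than in E3. They were probes of Zfp330, Rmdn3, Riok1, Actb and Sall4, and a probe of Mcm6 was lower in E3. In OG2 the probes of Rmdn3, Actb and Sall4 lay near their E3 level and that of Riok1 in between. The Zfp330 probe lay at 4.24 in OG2 and 4.21 in T9 against 9.48 in E3. The count of 6 was made after single discordant probes had been seen, on the same 2 arrays.

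The patterns below were picked from the results, and the HIF, immediate-early and ERK feedback lists were written after the first results. The ERK, brightness, collagen and differentiation tests were chosen after the result was seen; the harvest and HIF tests were set before the values they measure.

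Egr1 rose in EpiSC, and Fos lay 4.68 ± 0.54 above ESC on the log2 scale. An immediate-early response to the collagenase harvest was tested on 12 other immediate-early genes, with those already seen to be high left out. Leaving those out can lower the list. The median was 0.29 in E3 and 0.78 in T9, at percentiles 89.05 and 99.97 of matched random lists (at the bounds 0.22 and 0.29, at percentiles 90.6 and 97.1). In the EpiSC mean 9 members were higher, among them Egr2 (1.75), Ccn1 (1.55) and Zfp36 (1.20). The other 3 were lower, among them Gadd45b (-1.88). Egr2, Fosb, Ier2 and Egr3 were not above background in OG2, so they were measured only through EpiSC. Adjusted over the list alone, 0 were higher and 1 lower. The bound set beforehand was the 95th percentile in both lines, and by that bound alone this explanation would have been excluded; a margin of 1 bootstrap SE of the median (0.223 in E3, against a random 95th percentile of 0.395) was added after the value was seen, and within it the test does not decide. ERK inhibition by PD0325901 in the ESC medium was tested on 8 ERK feedback genes, all already seen in the FGF/ERK list. Their median was -0.26, with members on both sides, and -0.37 in E3 and -0.27 in T9, at percentiles 6.96 and 12.96. The bound for this explanation, above the 95th percentile in both lines, was not met. The bound against it, under the 5th percentile, was not met, so this test does not decide either. Harvest, medium and cell type changed together, so these explanations cannot be told apart here, and a difference between the cell types themselves stays open and untested.

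The glycolysis list lay above ESC in both EpiSC lines, with a median of 1.32. It lay at percentile 100 of lists matched on brightness in both lines, whose middle value was 0.062 for E3 and 0.052 for T9. After normalization, genes of like brightness thus did not share the shift. The percentile was already known when the list was picked, and quantile normalization itself evens out brightness. The percentile therefore does not decide on a brightness-dependent bias between the arrays. A wider hypoxia (HIF) programme was tested on 17 HIF targets outside glycolysis, without those already seen to be high: their medians of 1.14 in E3 and 1.07 in T9 were both at percentile 100 (at the bounds 0.91 and 0.88, at percentiles 99.99 and 100), with Vldlr at 2.99, Vegfa at 2.28. Of the 17, 13 were higher than in ESC, Car9 and Mxi1 with only 1 line above background, and 4 lower, Kdm3a (-0.58), Ak4 (-0.58), Angptl4 (-0.54) and Gys1 (-0.15). Of the 13, Car9, Car12, P4ha1, Egln1, Adm and Mxi1 were not above background in OG2, so the detection filter fixed their direction. The random lists were not matched on this. Members detected on all 3 arrays were the 4 lower ones and, on the higher side, Vegfa, P4ha2, Bhlhe40, Vldlr, Hilpda, Plod2 and Bnip3l. Over all probes 0 of the 17 passed the limma threshold, and 11 were higher adjusted over the list alone. As a hypothesis, a HIF programme may run higher in these EpiSC cultures; oxygen and cell density are not given in the sources used here, and feeders and medium changed with the cell type.

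All 12 measured primitive streak genes were higher in T9 than in E3, though some counted as measured only through detection in T9. Feeder fibroblasts carried over into T9 stay open: of the collagen genes Col1a1, Col1a2 and Col3a1, 1 (Col1a1) lay higher in T9, at 5.16 against a level in E3 not above background, with E3 minus T9 at -1.94 bead standard errors, and the others were not detected on any array. OG2, kept without feeders, had more Col1a1 (6.39), the fibroblast list was higher in T9 (median of E3 minus T9 -0.65 at percentile 0.01, or -0.37 at the bounds at percentile 0.165) and Thy1 was 4.10-fold higher in E3; a first comparison with OG2 gave 0 of 3, and E3 was taken in its place after that value was seen. A larger share of spontaneously differentiating cells in T9 may also raise other lineages, but the extraembryonic endoderm list lay at percentile 12.6 of matched random lists and only 3 neural genes were measured, so that stays open. An effect of the genetic backgrounds (hybrid and 129) was not tested, and neither was one of the line difference in Xist and the Y-linked Eif2s3y. With 1 array per line the difference in primitive streak genes has no replicate check.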
